A study of Oryctolagus cuniculus with 53 samples.

How the data were processed

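Total RNA from rabbit embryonic stem cells (ESC) and rabbit induced pluripotent stem cells (iPSC) was labelled with Cy3 and hybridised to 1-colour Agilent expression arrays, per the labels' protocols. The arrays were read with Agilent Feature Extraction 9.1, per the submitters' processing notes. The deposited values are on a log2 scale, with 1 value for each of 40884 probes on each of 53 arrays and 0 missing values. How the submitters scaled them is not given in the sources used here, and the values themselves were used to find out. The median of a deposited column lay between -0.08 and 0.04, so each array had been divided by a value near its own median. Taken out of the log and multiplied by 1 whole number per array, between 124 and 382 with a median of 172, 99.9964% of the 27760 probes whose identifiers start with A_ became whole intensities within a tolerance of 0.003. Of the other 13124 probes, with identifiers that start with CUST_, between 1.08% and 2.19% per array did so, and the reason was not tested. The whole number is called the scale factor below. The lowest recovered intensity on an array lay between 34 and 58 and never at 0, and no background subtraction was visible. Flags for spots above background or saturated were not used here.

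The array limits precision through its background. The 1st percentile of the recovered intensities, taken as the floor, lay between 48 and 70, and the array medians lay between 2.17 and 6.32 times that floor. A fold between a bright level and one close to the floor therefore understates the difference in RNA. For probes named in the text, the highest level on the dim side is given as a multiple of the floor where it was under 5 times the floor.

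The arrays were grouped from the sample titles by cell type, sorted population and line. Replicate arrays were compared before averaging, over the probes brighter than an intensity of 500 on every array. Arrays 1 and 2 of iPSC SSEA1+ line B29 differed with an SD of 0.12 on the log2 scale, against 0.28 to 1.01 for the other 51 replicate pairs, with a median of 0.54. They were averaged and counted as 1 sample, so that 52 samples entered the fits. The limit used, an SD under 0.2, was chosen after seeing the data, and counting both arrays separately was run as an alternative.

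All comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values without further scaling or filtering, and p-values were two-sided and adjusted over all probes by the Benjamini-Hochberg method, with a threshold of 0.05. For iPSC against ESC, the arrays of a line were first averaged, so that 4 ESC lines stood against 2 iPSC lines. For the comparisons of sorted populations and of lines, 1 mean per cell type, population and line was fitted over all 52 samples, which then shared 1 estimate of the spread between independent experiments, and each contrast averaged the differences within lines. Differences among the 4 ESC lines were tested with a moderated F test. Sets of probes were tested with camera, in limma, with a preset and with an estimated correlation between probes. These designs, the sample groups and most alternatives were fixed before the data were examined.

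The files do not pair the probes with genes, and 0 of the probe identifiers occur in the gene table at hand. The 28 gene lists chosen at that stage could therefore not be tested, and neither could the alternatives that average the probes of a gene. The rule for named genes required a gene symbol. It was applied without that condition and held to at most 2 identifiers per direction and comparison. The probes named are the largest rises and falls among those past the threshold whose line values did not overlap between cell types, or that went the same way in every line within a type. Where no probe passed, the largest changes are given as values. Several probes can stand for 1 transcript. Across samples, A_ probes with neighbouring numbers correlated with a median r of 0.98 over 4354 pairs, against 0.18 for random pairs of the same probes, and these correlations are across samples that share groups. Probe counts are therefore not gene counts. As a second count, probes with consecutive A_ numbers were taken as 1 run and each CUST_ probe as 1 run, which gave 25272 runs over the whole array.

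The fits were tested on simulated data with the real probes' levels and spread, in which 66 or 67 probes changed by each of 3 known amounts. With so few changed probes the adjustment is stricter than with many, so the shares below are not the limits of the real fits. The real fit of cell types in SSEA1+ cells called 10016 probes, of which 4490 changed at least 2-fold. For cell types, the simulated spread between lines was drawn from line means that already hold array noise. For iPSC against ESC in SSEA1+ cells over 40884 probes, 77.3% of probes with a simulated log2 change of 2, 0% of those with a change of 1 and 0% of those with 0.5 were recovered. For ESC SSEA1+ against SSEA1- over 40884 probes, the recovered shares were 98.5%, 86.6% and 23.9%. For iPSC SSEA1+ against SSEA1-/4- over 40884 probes, they were 93.9%, 53.7% and 2.99%, and for SSEA1+/4+ against SSEA1+ 89.4%, 41.8% and 7.46%. In no simulation were more than 10 unchanged probes called. The simulated noise was independent between probes and arrays, so nothing in it moved many probes of an array together. Random regroupings of the real iPSC arrays, given below, called up to 24269 probes. The simulations therefore do not bound false calls in the real data.

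Alternatives covered quantile normalization, median centring, a filter on dim probes, a trended and robust variance prior, a 2-fold threshold, other treatments of line and replicate number, and each array or line left out in turn. Added after seeing the data were normexp background correction with offsets of 50 and 10, the array floor as a covariate, the arrays with a scale factor over 250 left out, and arrays of 1 replicate number alone.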

Results

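Gene expression was measured in rabbit pluripotent stem cells of 2 kinds. ESC are cultured from embryos, and iPSC are made by reprogramming body cells. The 4 ESC lines carry the labels Line18, Line19, Line4 and Line8, and the 2 iPSC lines are B19 and B29. Cells were sorted on the stage-specific embryonic antigens SSEA1 and SSEA4, carbohydrate epitopes of the cell surface that are used to tell pluripotent cell populations apart. Each ESC line gave SSEA1+, SSEA1- and unsorted total (TOT) cells, and each iPSC line gave SSEA1+, SSEA1+/4+ and SSEA1-/4- cells. The design describes 3 independent experiments per line and population, and SSEA1- cells of Line4 had 2 arrays. In all there were 35 ESC arrays (12 SSEA1+, 11 SSEA1- and 12 TOT) and 18 iPSC arrays (6 per population). Arrays 1 and 2 of iPSC SSEA1+ line B29 differed far less than any other replicate pair and were counted as 1 sample. The files do not pair probes with genes, so probes are given by identifier.

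Arrays differed in brightness. A scale factor over 250 was found on 4 of 35 ESC arrays and 6 of 18 iPSC arrays, among them 3 of 6 iPSC SSEA1+ arrays and 0 of 12 ESC SSEA1+ arrays. The first principal component held 32.8% of the variance and the second 23.7%. A line through their plane parted all iPSC samples from all ESC samples. Within each type, samples with a scale factor over 250 tended to score high on the first component. In iPSC they lay at 94 to 174 and the others at 4.8 to 98. The order was looser in ESC, at -30 to 30 against -86 to 31. How much of the spread between experiments comes from brightness was not tested. Of the summed squares, cell type took 27.1%, line within type 9.25%, sorted population within type 11.6%, line by population 7.82% and the spread between experiments of 1 group 44.3%.

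**Figure D1:**
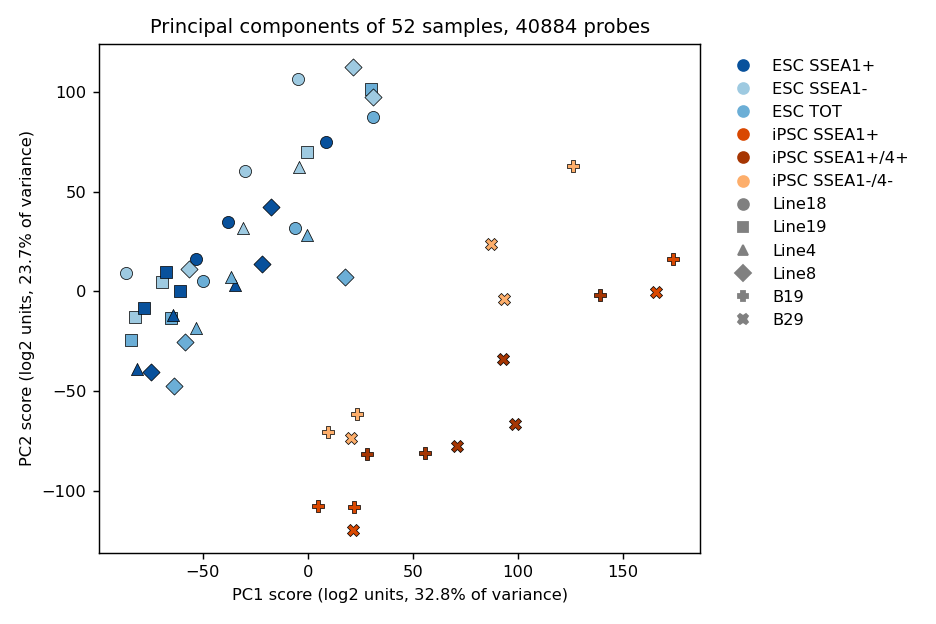
Scores of the 52 samples on PC1 (horizontal, log2 units, 32.8% of variance) and PC2 (vertical, log2 units, 23.7%), with colour for cell type and sorted population and symbol for line. The iPSC samples lie to the lower right of the ESC samples, and within each type the samples spread along a diagonal.

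The first comparison set the cell types side by side in SSEA1+ cells, the population that both share by name. In iPSC 5732 probes were higher and 4284 lower than in ESC, 10016 of 40884 probes (24.5%) in 6594 of 25272 runs. Of these, 4490 changed at least 2-fold and 365 at least 8-fold, 185 of them higher and 180 lower in iPSC. The largest rises were those of CUST_4636_PI427147524, with a mean log2 level of 7.50 ± 0.10 (SD, n = 2 lines) in iPSC against 0.62 ± 0.46 (SD, n = 4 lines) in ESC, a change of 6.88 ± 0.27 (SE, limma adjusted p = 2.39e-06), and of CUST_4879_PI427147524 (6.78 ± 0.32, SE, limma adjusted p = 6.02e-06). The largest falls were those of CUST_48_PI427147509, from 6.86 ± 0.29 in ESC to -1.16 ± 0.32 in iPSC (change -8.02 ± 0.22, SE, limma adjusted p = 7.24e-07), and of A_04_P002406 (-8.01 ± 0.22, SE, limma adjusted p = 7.24e-07). On iPSC SSEA1+ arrays these probes reached at most 2.46 and 2.58 times the array floor, so that the ESC signal stood next to a level close to background. By the rule that picked these 4 probes, their line means did not overlap between iPSC and ESC. The median over all probes was -0.15, and quantile normalization moved it to -0.0016 and gave 5018 higher and 4839 lower probes. The count depended on the iPSC lines, with 6360 probes without B19 and 4289 without B29, and fell to 1901 with the array floor as a covariate.

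In SSEA-negative cells (SSEA1- ESC and SSEA1-/4- iPSC, with SSEA4 used in the iPSC gate only, since the ESC lines lacked SSEA4 according to the labels), 2395 probes were higher and 1766 lower in iPSC, 4161 in all and 2819 runs. A change of at least 2-fold was seen for 2684 and of at least 8-fold for 212. CUST_3772_PI427147524 rose most, by 6.20 ± 0.45 on the log2 scale (SE, n = 2 and 4 lines, limma adjusted p = 0.00011), followed by CUST_4879_PI427147524 at 5.79 ± 0.41 (SE, limma adjusted p = 8.99e-05). A_04_P002406 changed by -7.11 ± 0.50 and CUST_48_PI427147509 by -6.87 ± 0.51 (SE, limma adjusted p = 8.42e-05 and 0.00012), with levels in iPSC of at most 4.81 and 4.61 times the floor. The 2 comparisons use the same lines, so that shared calls are not independent. Of the calls, 1943 were higher in both and 1476 lower in both, where independent lists would share 335.8 and 185.0, and 17 went opposite ways. Across probes, which are not independent replicates, the 2 sets of differences correlated with r = 0.81. In a check chosen after seeing the data, with SSEA1+ cells of 1 iPSC and 2 ESC lines set against negative cells of the other lines, so that no line was shared, r lay between 0.640 and 0.772 over 12 pairings (median 0.719). The count was 2014 without B19 and 1304 without B29, and 7374 when the arrays were fitted with line as a random block. In that fit the correlation within lines was estimated at -0.042, so arrays in effect counted as replicates of the cell type.

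**Figure D2:**
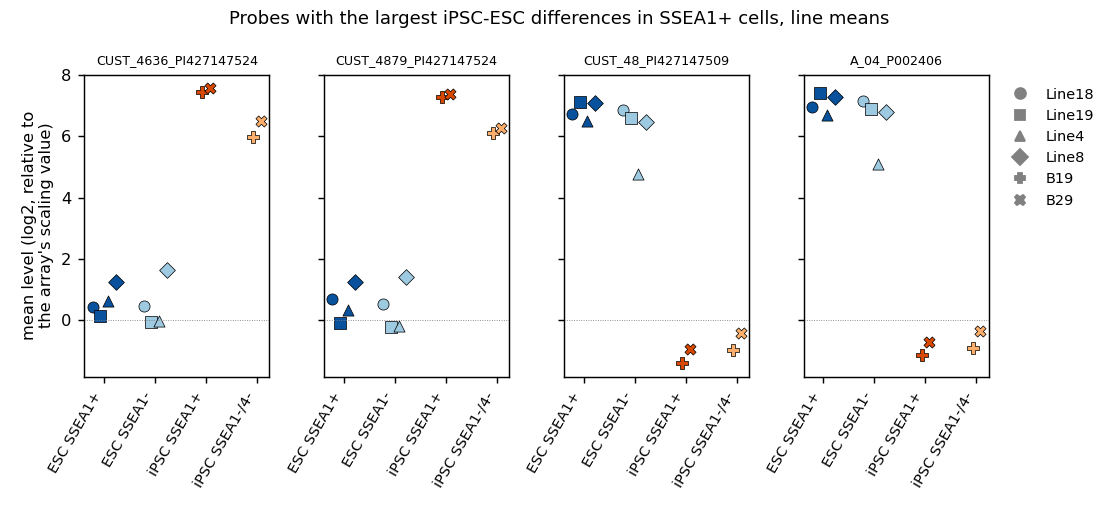
Mean log2 level (vertical, relative to the array's scaling value) of the 4 probes with the largest iPSC-ESC differences in SSEA1+ cells, by cell type and population (horizontal), with 1 point per line. CUST_4636_PI427147524 and CUST_4879_PI427147524 lie at 5.98 or more in both iPSC populations shown and at 1.65 or less in both ESC populations, and CUST_48_PI427147509 and A_04_P002406 show the opposite order.

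Whether the step from negative to SSEA1+ cells differed between the types was tested directly. The change was more negative in iPSC for 37 probes and more positive for 0, in 26 runs, with 3746 probes at an unadjusted p under 0.05 in limma. The split was less one-sided in other fits. With arrays as independent samples 92 were more positive and 283 more negative, and with line as a random block 90 and 278. The correlation within lines was estimated at -0.013 in the latter, so both in effect counted arrays as replicates. Counting the close arrays separately gave 24 and 107, and the trended prior 2 and 5. CUST_2150_PI427147524 changed by -4.29 ± 0.44 (SD, n = 2 lines) in iPSC and by 0.19 ± 0.50 (SD, n = 4 lines) in ESC, a difference of -4.47 ± 0.35 (SE, limma adjusted p = 0.0102). CUST_2683_PI427147524 changed by -4.06 ± 0.24 in iPSC and by 0.01 ± 0.53 in ESC (difference -4.07 ± 0.34, SE, limma adjusted p = 0.0134). In limma 0 probes passed without B19, without B29, with the array floor as a covariate or without the bright arrays (3187, 1820, 2053 and 2725 at an unadjusted p under 0.05), and 57 passed without Line8. The calls ended but the changes of both named probes did not shrink with the floor covariate in this fit of 6 line means, at -4.75 and -4.12 (limma adjusted p = 0.326 and 0.361).

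Within the ESC lines, SSEA1+ and SSEA1- cells differed less than the cell types did. In SSEA1+ cells 458 probes were higher and 332 lower, 790 in all and 517 runs, and 642 of them went the same way in all 4 lines. At least 2-fold changes were more often falls, with 49 probes higher and 138 lower, and none of the probes reached 8-fold (0). CUST_8446_PI427147524 rose from 1.01 ± 0.72 (SD, n = 11) to 3.46 ± 0.85 (SD, n = 12), a change of 2.42 ± 0.24 (SE, limma adjusted p = 3.32e-08), and CUST_6432_PI427147524 rose by 2.14 ± 0.27 (SE, limma adjusted p = 1.75e-06). A_04_P001711 changed by -2.54 ± 0.55 and CUST_8379_PI427147524 by -2.47 ± 0.25 (SE, limma adjusted p = 0.00723 and 3.88e-08), the latter at most 4.63 times the floor in SSEA1+ cells. The number of calls within single lines was 359 in Line8, 85 in Line18, 28 in Line19 and 6 in Line4. The median over all probes was 0.13, and quantile normalization moved it to 0.02. The balance of rises and falls was not stable: 621 higher and 627 lower after quantile normalization, 476 and 531 with the array floor as a covariate, 87 and 183 without Line18, 102 and 276 without Line4, 54 and 97 without Line8, and 1306 and 334 without Line19. With the 4 line means as the only replicates 0 probes passed, with 4891 at an unadjusted p under 0.05 in limma, and the count was 151 without Line8, 270 without Line18, 378 without Line4 and 1640 without Line19. Leaving out array 3 of Line8 SSEA1- gave 1706 probes, and leaving out 13 other single arrays gave 372 to 514.

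Within the iPSC lines, SSEA1+ and SSEA1-/4- cells differed at 2405 probes (1636 runs), 1333 higher and 1072 lower in SSEA1+. This fit took its spread from all 52 samples, 35 of them ESC. As given below, 10 of 100 splits of the arrays, the real one included, reached this count. All 105 probes that changed at least 8-fold were lower in SSEA1+ cells. CUST_231_PI427147524 changed from 4.42 ± 1.21 (SD, n = 6) to -0.21 ± 0.82 (SD, n = 5), a fitted change of -4.49 ± 0.56 (SE, limma adjusted p = 2.08e-07), and CUST_2150_PI427147524 changed by -4.29 ± 0.31 (SE, limma adjusted p = 5.74e-13). The largest rises were 2.30 ± 0.31 for CUST_457_PI427147524 and 2.12 ± 0.31 for CUST_331_PI427147524 (SE, limma adjusted p = 1.06e-06 and 8.17e-06). The count was 677 without B29 (175 higher, 502 lower) and 1016 without B19 (446 higher, 570 lower). It was 1518 without array 2 of B29 SSEA1-/4- (664 higher, 854 lower), and at least 2-fold 494 were higher and 747 lower. Quantile normalization turned the split to 1154 higher and 1528 lower. A fit of these 2 populations alone, with their own spread and fewer samples, gave 452 probes, 80 higher and 372 lower. With the array floor as a covariate the count was 4211, with 2569 higher and 1642 lower.

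The ESC and iPSC sorts moved many of the same probes. Of the probes higher in ESC SSEA1+ cells, 199 were also higher in iPSC SSEA1+ cells and 4 lower, and of those lower in ESC SSEA1+ cells 140 were lower and 7 higher in iPSC. Independent lists would share 14.9 higher and 8.71 lower. The 458 probes higher in ESC SSEA1+ cells had a median change of 0.70 in iPSC, 0.48 in B19 and 0.94 in B29 (camera in limma, p = 1.32e-45 with the preset correlation and p = 0.035 with an estimated correlation). The 332 lower probes had a median of -0.71, -0.64 in B19 and -0.70 in B29 (p = 4.73e-63 with the preset correlation and p = 1.45e-05 with an estimated correlation). The probes called in iPSC, followed in ESC, had medians of 0.28 for the higher and -0.19 for the lower set (p = 0.0473 and 0.000255 with an estimated correlation). These sets were chosen on this series, in cells other than those they were measured in, and all 4 medians kept their sign after quantile normalization.

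SSEA1+/4+ iPSC were set against SSEA1+ iPSC. The labels do not say whether the SSEA1+ population excluded cells with SSEA4, so the comparison may set overlapping populations side by side. Between SSEA1+/4+ and SSEA1+ cells 0 probes passed in limma, with 1719 at an unadjusted p under 0.05 and a lowest adjusted p of 0.454. The largest differences, none of them past the threshold, were 2.87 ± 0.93 for A_04_P068267 and 2.65 ± 0.81 for A_04_P005471 (SE, both limma adjusted p = 0.848), and -1.64 ± 0.98 for A_04_P043957 and -1.61 ± 0.73 for CUST_5192_PI427147524 (SE, both limma adjusted p = 1). A count of 0 was not a firm limit. With line means paired by line 1435 probes passed (1034 higher, 401 lower), and 222 probes (204 higher, 18 lower) passed with the array floor as a covariate and 380 (352 higher, 28 lower) without the bright arrays. Single omissions gave 36 without array 2 of B19 SSEA1+, 14 without the averaged sample of B29 SSEA1+ and 3 without B19.

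SSEA1+/4+ cells differed from SSEA1-/4- cells at 2672 probes (1824 runs), 1457 higher and 1215 lower, and all 103 changes of at least 8-fold were falls. A_04_P067167 rose by 2.17 ± 0.35 and A_04_P087427 by 1.90 ± 0.27 (SE, limma adjusted p = 3.58e-05 and 3.67e-06). A_04_P005095 changed by -4.55 ± 0.55 and A_04_P102803 by -4.52 ± 0.47 (SE, limma adjusted p = 9.55e-08 and 3.29e-09). With SSEA1+ cells against the same negatives, 821 higher and 935 lower calls were shared, against 47.5 and 31.9 for independent lists. Simulations of unchanged groups that share the negatives gave 0 shared calls. That was fixed in advance, since unchanged groups with independent noise give hardly any calls. The changes correlated with r = 0.80 and a covariance of 0.169, against 0.471 and 0.0369 in those simulations. With the negatives split by line, 78 higher and 303 lower calls were shared between SSEA1+ of B19 and SSEA1+/4+ of B29, and 26 and 229 the other way round. Quantile normalization turned the split to 1041 higher and 1757 lower. A fit of these 2 populations alone, with their own spread and not that of all samples, gave 1200 probes, 437 higher and 763 lower. The count was 421 without B29 (46 higher, 375 lower) and 1174 without B19 (460 higher, 714 lower). At least 2-fold 428 were higher and 717 lower, while the array floor as a covariate gave 2867 higher and 1871 lower. Without array 2 of SSEA1+/4+ B19, SSEA1-/4- B29 or SSEA1+/4+ B29 the count was 1768, 1385 and 1612.

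**Figure D3:**
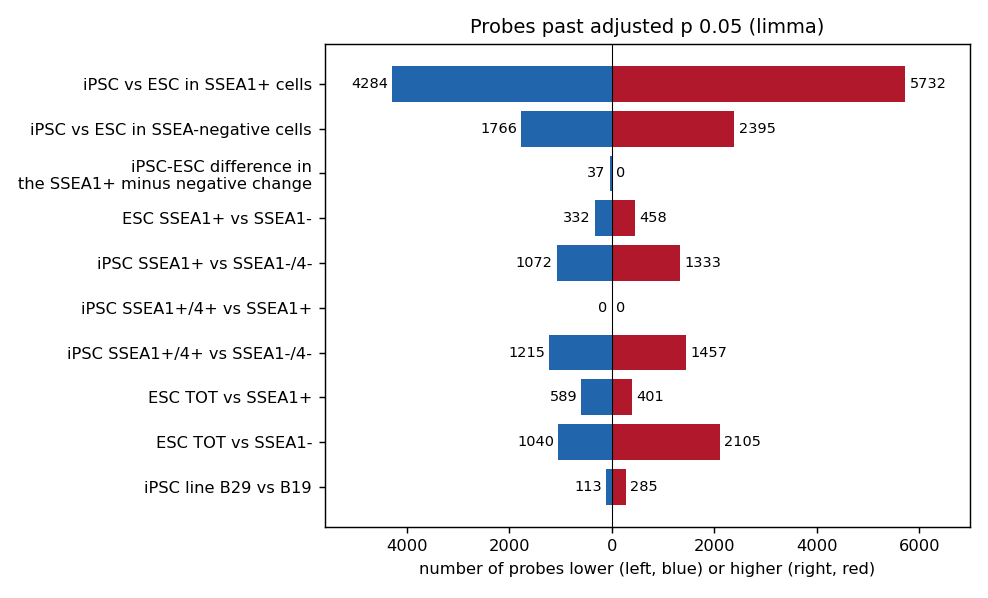
Number of probes (horizontal) with an adjusted p under 0.05 in limma for each comparison (vertical), with probes higher in the first-named group in red to the right and lower in blue to the left. The cell types differ at the most probes, 5732 higher and 4284 lower in SSEA1+ cells, and SSEA1+/4+ against SSEA1+ iPSC shows 0.

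Unsorted ESC were set against both sorted populations. Against SSEA1+ cells, 401 probes were higher and 589 lower in TOT (990, 655 runs), but at least 2-fold 137 were higher and 80 lower. Against SSEA1- cells 2105 were higher and 1040 lower (3145, 2134 runs), but at least 2-fold 211 were higher and 232 lower. A_04_P000286 had a mean level of 5.63 ± 0.91 (SD, n = 12) in TOT, 2.02 ± 0.66 (SD, n = 12) in SSEA1+ and 1.52 ± 0.95 (SD, n = 11) in SSEA1- cells, changes of 3.61 ± 0.22 and 4.11 ± 0.23 (SE, limma adjusted p = 7.89e-15 and 2.36e-16). A_04_P000289 was higher than in SSEA1+ cells by 3.62 ± 0.22 and A_04_P000287 higher than in SSEA1- cells by 4.21 ± 0.24 (SE, limma adjusted p = 7.89e-15 and 3.30e-16). A_04_P034347 and A_04_P034348 were lower than in SSEA1+ cells, by -2.21 ± 0.31 and -2.20 ± 0.30 (SE, limma adjusted p = 8.63e-06 and 4.99e-06). CUST_1129_PI427147524 was lower than in SSEA1- cells by -2.34 ± 0.24 and A_04_P034348 by -2.24 ± 0.31 (SE, limma adjusted p = 1.00e-08 and 3.70e-06).

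TOT lay beyond both sorted populations at many probes. It was higher than both at 271 probes, 253 of them in all 4 lines, and lower than both at 327, 292 of them in all 4 lines. These counts were 485 and 695 after quantile normalization and 484 and 543 with the array floor as a covariate. Independent lists would share 20.6 and 14.98. Simulated unchanged groups sharing the TOT arrays shared 0, which was fixed in advance, since such groups with independent noise give hardly any calls. A difference of at least 2-fold from both populations was seen at 64 higher and 49 lower probes. With TOT against SSEA1+ taken from Line18 and Line19 and TOT against SSEA1- from Line4 and Line8, 66 higher and 19 lower calls were shared and 4 went opposite ways, and 44 and 85 were shared with the lines exchanged. Across all probes, which are not independent replicates, these differences correlated with r = 0.0810 in the first case and 0.589 in the second. Over all probes and lines the 2 differences correlated with r = 0.52 and a covariance of 0.0405, against 0.484 and 0.0185 in the simulations. Without Line18, Line19, Line4 or Line8, the count against SSEA1+ cells was 458, 543, 491 and 642, with 292 higher and 199 lower without Line4. Against SSEA1- cells it was 1509 without Line18, 1038 without Line8 and 2058 without array 2 of Line4 SSEA1-, and quantile normalization narrowed that split to 2311 higher and 1963 lower.

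**Figure D4:**
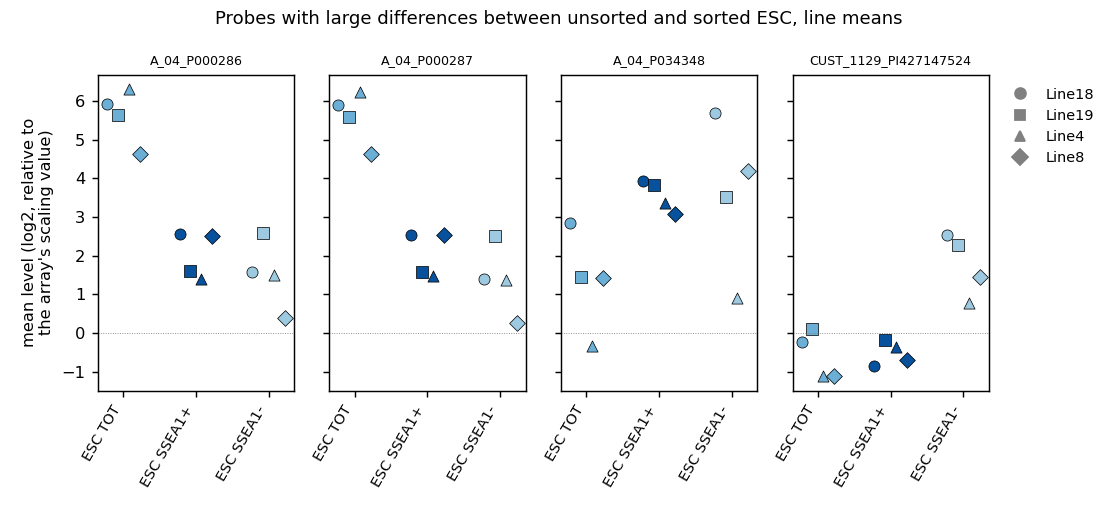
Mean log2 level (vertical, relative to the array's scaling value) of 4 probes in TOT, SSEA1+ and SSEA1- ESC (horizontal), with 1 point per line. A_04_P000286 and A_04_P000287 lie at 4.62 or more in TOT cells of all 4 lines and at 2.60 or less in the sorted cells, and CUST_1129_PI427147524 lies at 0.78 or more in SSEA1- cells and at 0.11 or less in the rest.

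Lines of 1 cell type differed as well. Among the 4 ESC lines 2524 probes (1802 runs) differed, 1221 with at least 2-fold and 100 with at least 8-fold between the highest and the lowest line. CUST_1310_PI427147524 was at 5.66 ± 0.63 (SD, n = 9) in Line18 and at -1.51 ± 0.39 (SD, n = 9) in Line8, a range of 7.17 (limma F test, adjusted p = 2.08e-29). CUST_455_PI427147524 was at 5.42 ± 0.23 (SD, n = 8) in Line4 and at -1.61 ± 0.35 (SD, n = 9) in Line8 (limma F test, adjusted p = 4.07e-31). On the dim line the 2 probes reached at most 1.38 and 1.19 times the floor. Between pairs of ESC lines, 558 probes (Line19 and Line4) to 1455 probes (Line18 and Line4) passed. Quantile normalization raised the count among the 4 lines to 4292, and SSEA1+ arrays alone gave 405.

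Between the iPSC lines 398 probes (268 runs) differed, 285 higher and 113 lower in B29. CUST_3399_PI427147524 was higher in B29 by 3.97 ± 0.29 and CUST_5173_PI427147524 by 2.85 ± 0.30 (SE, limma adjusted p = 3.13e-13 and 1.09e-08). CUST_9115_PI427147524 was at -1.67 ± 0.34 (SD, n = 8) in B29, at most 1.25 times the floor, and at 3.05 ± 0.46 (SD, n = 9) in B19, a change of -4.74 ± 0.19 (SE, limma adjusted p = 2.67e-21). CUST_1672_PI427147524 changed by -3.66 ± 0.16 (SE, limma adjusted p = 3.06e-20) and reached at most 2.33 times the floor in B29. SSEA1+ arrays alone gave 52 probes, and the array floor as a covariate gave 680.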

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

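The tests of array brightness on the called probes, of cell gates shared by both types, of brighter iPSC arrays, of handling, the jackknife, and all counts over other splits were chosen after the results were seen. The tests of brightness in other splits, of leaving out other samples in place of the bright arrays, of the spread between lines and of cells in neither gate were written down before their values were known, the second of them when the calls kept without the bright arrays had been seen.

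The change from negative to SSEA1+ cells differed between iPSC and ESC at 37 probes, by a test of the difference itself. Between lines of 1 type, the change from SSEA1- to SSEA1+ cells differed among the 4 ESC lines at 84 probes and the change from SSEA1- to TOT cells at 26 probes, by a limma F test of that difference. No such probe was found for TOT against SSEA1+ cells (0, with 437 at an unadjusted p under 0.05) or, by limma, in the 3 iPSC comparisons (0 each, with 924, 124 and 774 at an unadjusted p under 0.05).

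Single values far from their group were found in 4 of 58 groups of 4 to 10 values, where chance alone marks about 1 in 20. CUST_3772_PI427147524 in SSEA1- ESC was at 3.13 in Line8 and at 1.35 to 1.51 in the other lines. CUST_331_PI427147524 was at 5.12 in array 1 of B19 SSEA1+ and at 6.82 to 7.22 in the other SSEA1+ samples, and at 5.38 in array 3 of B29 SSEA1-/4- against 4.34 to 4.64 in the others. CUST_5173_PI427147524 was at 6.31 in array 3 of B19 SSEA1-/4- and at 0.42 to 3.38 in the other B19 samples.

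Other groupings of the same samples tested whether a count could come from chance. With 15 ways to part 6 lines into 4 and 2, no share under 0.05 can be reached. The real split gave 10016 probes in SSEA1+ cells, 4161 in negative cells and 37 for the difference between these, and the highest other split gave 1, 2 and 0, with 1 split as large as the real one each time. Regrouping within lines, 1 of 100 splits, the real one, reached the count for ESC SSEA1+ against SSEA1- (790, highest other 72), TOT against SSEA1+ (990, highest other 62) and TOT against SSEA1- (3145, highest other 2695), and regrouping within populations 1 of 100 reached that among the ESC lines (2524, highest other 1099). For SSEA1+/4+ against SSEA1-/4- it was 2 of 100 (2672, highest other 3187). At most 2 of 100 splits thus reached these 5 counts, so a random grouping of arrays rarely gave as many. Other splits of TOT and SSEA1- and of SSEA1+/4+ and SSEA1-/4- still came close to or passed the real count. These draws regroup single arrays, so they say nothing on how other lines would behave. The shares were not adjusted for the number of counts looked at. Without a covariate, a random grouping of arrays gave as many more often for iPSC SSEA1+ against SSEA1-/4- (10 of 100, 2405, highest other 19609) and B29 against B19 (8 of 100, 398, highest other 24269). For these 2 counts chance among arrays cannot be excluded. For SSEA1+/4+ against SSEA1+ the real count was 0, which all 100 of 100 splits reach by construction, so the draws say nothing about it (highest other 14892). With the array floor as a covariate, chosen after seeing the data, the same draws reached the real count in the real split only for iPSC SSEA1+ against SSEA1-/4- (1 of 100, 4211, highest other 2056) and B29 against B19 (1 of 100, 680, highest other 537). They gave 2 of 100 for SSEA1+/4+ against SSEA1+ (222, highest other 672) and 3 of 100 for SSEA1+/4+ against SSEA1-/4- (4738), where the highest other split rose to 6633.

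Splits that call many times the real count show a structure among the iPSC arrays that the populations do not follow: in the split with 19609 probes, 3 of 5 samples on one side and 1 of 6 on the other had a scale factor over 250, and mean floors were -2.18 and -1.52, against -1.81 and -1.82 for the real populations. With the array floor as a covariate, 1 of 100 splits reached the real count, which is what array brightness predicts for the other splits of this sort, but splits that pass the real count remained in both comparisons of SSEA1+/4+ cells (672 against 222, 6633 against 4738), so brightness does not account for the structure of all iPSC arrays. With the covariate 100% of the 2405 probes kept call and direction. This cannot decide whether brightness made the real calls. The mean floors of the 2 populations were alike, so the covariate could hardly shift the changes and mainly lowered the spread. Without the bright arrays 1135 of them (47.2%) were still called and 100% kept their direction, with a median change 0.917 times the first, and 11 of 100 draws that left out 1 other sample of each of the same groups kept as few (984 to 1719, changes 0.958 to 1.16 times the first), so brightness may add slightly to the size of the changes. The 199 probes higher in SSEA1+ cells of both types were consistent with a sort that parts like cells in both, as a hypothesis.

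More probes separated the cell types in SSEA1+ than in negative cells, 2.41 times as many. A wider spread between lines in the negative cells (median residual SD 0.219 against 0.188) was weighed as the cause. Tested with the SSEA1+ spread, the negative differences gave 6309 probes. The limit set beforehand, a ratio of 1.5, asked for 6677, so it was missed. The ratio of the counts was 1.59, and 1.51 to 1.69 with 1 ESC line left out. Its jackknife SE over the ESC lines, added after the results were seen, was 0.117. The ratio was thus not apart from 1.5, and this cause stays open. The SSEA1+ differences tested with the negative spread gave 7567 probes, against 4161 in negative cells, so an excess remained after that exchange. Whether array brightness is the cause stays open as well. Without the bright arrays the ratio was 2.62, so the excess was also seen where iPSC SSEA1+ arrays were not the brighter ones. Their mean floor moved from -1.83, below the -1.54 of ESC, to -1.37, above it. An imbalance in brightness thus remained, in the other direction. With the array floor as a covariate the order of the counts turned, 1901 in SSEA1+ and 2833 in negative cells, in a fit of 6 line means where floor and type go partly together. A larger difference between the types in SSEA1+ cells (4766 probes with a log2 difference of at least 1, against 3302) stays open, and the test of the difference itself called 37 probes.

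Unsorted ESC lay beyond both sorted populations at 271 higher and 327 lower probes (485 and 695 after quantile normalization, 484 and 543 with the array floor as a covariate). With the array floor as a covariate 100% of these probes stayed beyond both, but this cannot decide on array brightness. TOT arrays lay between the sorted populations in brightness, with a median scale factor of 165, against 162 in SSEA1+ and 188 in SSEA1- cells. The covariate could therefore hardly remove such probes. Cells collected in neither gate could give such values and stay open. If those cells lacked the transcripts altogether, the probes lower than both would need them to make up a median of 36.2% of TOT. The most demanding probe would need 78.3%. These shares are minima, taken against the nearer sorted population and from values that hold background. A single share for all probes would have to reach the highest of them, which rests on 1 probe. Handling during staining and sorting cannot be told apart from cells outside both gates. No ESC stained and passed through the sorter without a gate are described among the samples. Over the 84 probes higher in TOT of Line18 and Line19, sorted iPSC lay 0.67 above the sorted cells of Line4 and Line8. That value compares cell types, so it cannot decide on handling.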

How the results depend on the processing

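The array floor, bright arrays, normexp, separate counting of the 2 close arrays and single replicate numbers were chosen after seeing the data. Of 147 counts under settings other than leaving out samples, 92 stayed within 1.5 times the first value. For the rest the cause was not tested unless named. In the order of the report (SSEA1+ types, negative types, their difference, ESC sort, iPSC SSEA1+ sort, SSEA4, SSEA1+/4+ sort, TOT against SSEA1+, TOT against SSEA1-, ESC lines, iPSC lines), a 2-fold threshold, which can only lower counts, gave 4490, 2684, 37, 187, 1241, 0, 1145, 217, 443, 1221 and 213. Quantile normalization gave 57 for the difference, 1248 for the ESC sort, 1989 for TOT against SSEA1+ and 4292 for the ESC lines. The difference between types was the least steady: 65 without the dimmest probes, 7 (2 more positive, 5 more negative) with the trended prior, 131 with the close arrays counted separately, 59 and 167 with normexp offsets of 50 and 10, 375 with arrays as independent samples, 368 with line as a random block and 0 with the floor as a covariate or without bright arrays (2053 and 2725 at an unadjusted p under 0.05 in limma). The floor as a covariate gave 1901 for SSEA1+ types, 4211 and 4738 for the iPSC sorts, 222 for SSEA4, 1510 and 4965 for TOT, 3945 for the ESC lines and 680 for the iPSC lines. Without bright arrays the ESC sort gave 1231, the iPSC SSEA1+ sort 1455, SSEA4 380 and the iPSC lines 253. Arrays numbered 1, 2 and 3 alone, with 1 array per line, gave 1616, 24555 and 4226 for SSEA1+ types. Number 2 gave 6687 higher and 17868 lower, the opposite order to numbers 1 (881 and 735) and 3 (2818 and 1408). Both iPSC arrays numbered 2 were bright. For negative types, numbers 1 and 2 gave 1482 and 592, and arrays as independent samples or with line as a random block gave 6663 and 7374. With line as a random block, the correlation within lines was estimated at -0.097 (SSEA1+ types), -0.042 (negative types) and -0.013 (difference). These fits thus in effect counted arrays, not lines, as replicates. Line means paired by line, with fewer samples, gave 0 for the ESC sort (4891 at an unadjusted p under 0.05 in limma), 5627, 1435 and 7998 for the iPSC sorts and 1538 and 1458 for TOT. Only the 2 populations compared gave 1435 for the ESC sort, 452 (80 higher, 372 lower) and 1200 (437 higher, 763 lower) for the iPSC sorts and 1543 for TOT against SSEA1+. SSEA1+ arrays alone gave 405 for the ESC and 52 for the iPSC lines.

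The replicate numbers were not used to pair samples, since the labels do not say what they share. Deviations from the group means correlated with a median r of 0.27 between samples of the same line and number, from -0.68 to 0.78, and 32 of 50 such pairs lay over 0.1. Other lines with the same number had a median r of 0.25 (244 of 375 over 0.1), and other numbers of the same line -0.13, so that numbers deviated together across lines too. With the replicate number as a block and line as a random block, negative types gave 7033, the difference 578 (186 more positive, 392 more negative) and SSEA1+ types 11067, where line as a random block alone had given 7374, 368 and 11415. With the replicate number within each line as a block, the ESC sort gave 1123, the iPSC sorts 2558, 0 and 3377, and TOT 1324 and 3783. With the replicate number as a block across lines, the ESC lines gave 3587 and the iPSC lines 571. Only negative types and the difference moved by over 1.5 times the first value. Against line as a random block alone, only the difference did. Of 52 samples, 32 correlated best with their own number, with at most 3 numbers to choose from. No value for chance was computed. This is a hint from the data that numbers share something, which the design does not state.

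Leaving out 1 line gave 4289 to 10354 for SSEA1+ types, 1304 to 4909 for negative types and 0 to 57 for their difference, where a lone iPSC line is assumed to vary as the ESC lines do. Leaving out 1 line or array gave 151 to 1706 for the ESC sort, 677 to 3039 for the iPSC SSEA1+ sort, 0 to 36 for SSEA4, 421 to 3674 for the SSEA1+/4+ sort, 458 to 1060 and 1038 to 4155 for TOT, 2207 to 2731 for the ESC lines and 296 to 448 for the iPSC lines. In the ESC sort the single arrays that moved the count were SSEA1- array 2 and SSEA1+ arrays 2 and 3 of Line18, SSEA1- array 1 and SSEA1+ array 3 of Line19, SSEA1- arrays 1 and 2 and SSEA1+ arrays 2 and 3 of Line4, and SSEA1- arrays 1, 2 and 3 and SSEA1+ arrays 1 and 3 of Line8. Of 80 named-probe values under quantile normalization or the floor covariate, 76 kept direction and side of the threshold. With the covariate the 2 probes of the difference between types lost it (limma adjusted p = 0.326 and 0.361) at changes of -4.75 and -4.12, and A_04_P068267 and A_04_P005471 passed it for SSEA4 (limma adjusted p = 0.0348 and 0.0343). After quantile normalization these limma adjusted p were 0.0158, 0.00762, 0.669 and 0.651. Probes beyond both sorted populations in TOT numbered 485 higher and 695 lower after quantile normalization and 484 and 543 with the covariate. Values averaged per gene, gene lists and their alternatives were not run, since no probe had a gene name. Arrays whose median lies only 2.17 times above the floor limit what can be seen at dim probes.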

Other observations

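All tests and values in this part were chosen after seeing the data. Several line differences were close to on or off. CUST_455_PI427147524 was at 5.19 to 5.63 in all 3 populations of Line4 and at 5.17 to 5.45 in all populations of both iPSC lines, and between -1.83 and -1.16 in Line18, Line19 and Line8. CUST_9115_PI427147524 was between -1.89 and -1.53 in the 3 populations of iPSC line B29 and at 2.75 to 4.58 in all populations of the 5 other lines. Among the 4 ESC lines, Line8 was at least 8-fold below each other line at 10 probes and Line19 at least 8-fold above each other line at 7. No genotype or sex of the lines was analysed here.

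The probes at which unsorted ESC lay beyond the sorted cells were also measured in iPSC. The 84 probes higher and 40 lower in TOT of Line18 and Line19 were, in sorted iPSC against the sorted cells of Line4 and Line8, at medians of 0.67 and -1.26. The 58 higher and 56 lower probes of Line4 and Line8 were at 1.06 and -1.66 against the sorted cells of Line18 and Line19. No no-change value that allows for probes of 1 transcript moving together was computed, so these are values only.

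The position of TOT along the sort was taken from probes called in the other 3 ESC lines. Where probes were chosen as higher in SSEA1+ cells, TOT lay 1.05 above SSEA1- cells in Line18, 0.81 in Line4 and 1.35 in Line8, and SSEA1+ cells lay 0.94, 1.08 and 1.23 above. In Line19 the 1154 probes chosen in this way differed between its own SSEA1+ and SSEA1- cells by a median of 0.03 only. For probes chosen as lower in SSEA1+ cells, the median difference from SSEA1- cells was -0.33 in TOT and -0.68 in SSEA1+ cells of Line18, -0.19 and -0.33 in Line19, -0.25 and -0.29 in Line4, and -1.39 and -0.86 in Line8.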
